A study of Mus musculus with 4 samples.

How the data were processed

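RNA sequencing was carried out on cultured mouse vascular smooth muscle cells, the contractile cells of the arterial wall, from C57BL/6 mice at passages 4 to 10, per the labels. The cells received either a scramble siRNA, a control with no intended target, or an siRNA against circEsyt2, a circular RNA named after the gene Esyt2, for 48 hours. Each group has 2 libraries, and groups and replicate numbers were taken from the sample titles. No label says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The protocols describe total RNA, first- and second-strand cDNA synthesis and a library kit that cuts and tags double-stranded cDNA. Paired reads of 150 bp were produced, per the labels. Neither a strand setting nor a step removing linear RNA or ribosomal RNA is given in the sources used here.

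The values deposited by the authors are FPKM, fragments per kilobase of gene length scaled by the fragment total of the library, with 1 file per library and 1 row per gene symbol and Entrez identifier. Trimmomatic (read trimming), HISAT2 (alignment) and featureCounts (counting per gene) are named with GRCm38 and mm10 in the submitters' processing notes. Their versions and settings, and the annotation release, are not given in the sources used here. Each file lists 22488 genes, of which 20745 are above 0 in at least 1 library. FPKM divides by gene length and library total, so values can be compared between libraries for a gene, but a few abundant genes can shift all others. A gene table of this kind counts fragments over all exons of a gene, so it does not separate the circular transcript of Esyt2 from the linear one, and no value for circEsyt2 itself is given.

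The depth behind each value was recovered from its digits. An FPKM is a whole number of fragments divided by a whole-number length and library total, so the library totals were solved with the exon-union lengths of GENCODE mouse release M21. For each gene the smallest length that made its fragment numbers whole was solved. The M21 exon-union length was used instead where it was a whole multiple of that length, as in 96.5% of the genes above 0. All 70649 values above 0 gave a whole fragment number within a tolerance of 0.0001, which this way of solving largely builds in. The totals were 2516428 and 4116791 fragments for scramble replicates 1 and 2, and 3765056 and 3127224 for circEsyt2 siRNA replicates 1 and 2. Of each total, 99.95% to 99.96% lay in the listed genes. The totals therefore count fragments assigned to genes, and the number of fragments sequenced is not known from them. At these depths 1 fragment in a gene of 1 kb is worth 0.243 to 0.397 FPKM. Floors and fragment numbers cover counting error only, since reads without molecular identifiers are not independent molecules. Genes were matched to M21 by symbol (22391 found, 99.6%), and coordinates are 1-based on GRCm38 from that annotation.

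The main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(FPKM + 1) for the 11290 genes with a mean FPKM of at least 1 over the 4 libraries. Tests were two-sided, with p adjusted by the Benjamini-Hochberg method over all genes tested and a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 5 tested members, and again with an estimated correlation and with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit, so few lists can pass it. The 26 lists, the test, its threshold, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Esyt2, Pcbp1 and Trp53. It added the 8 called genes with the largest rise and the 8 with the largest fall, at an absolute log2 fold change of at least 1 with no overlap between groups, passing over predicted genes, Rik clones and pseudogenes. It also named the 2 members with the smallest p from each main list and from each context or cell type list called by camera. Other genes are named in the text as chosen after their values were seen. Fragments of overlapping genes cannot be told apart where strand is not used, which touches Pcbp1, Ndrg1, Cxadr, Fst, Gas1, Cdc20, Hnrnpd and Ddit3 among the genes named.

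The steps were tested on simulated fragments for the real genes, with 200 genes changed. Among the genes changed by a log2 fold change of 1, limma recovered 47.5% of 99, and at a log2 fold change of 2 it recovered 98.0% of 100, with 13 of 11087 unchanged genes called. On the same simulated fragments limma's voom recovered 77.0% of 100 and 100% of 100. The unchanged genes that voom called were not counted. A list of 30 genes lowered by 0.5 had a camera p of 9.25e-14. Each gene was simulated independently, with the same dispersion (0.0185) in all 4 libraries. Among the real lists the estimated correlation reached 0.412 for interferon genes and 0.416 for collagens, though it was near 0 for others. The real circEsyt2 siRNA replicates also differed more than the scramble replicates. The simulation covers neither condition, so its values do not show how the tests behave under them. Alternatives covered pseudocounts of 0.1 and 0.5, no filter and a mean FPKM of at least 5, and 4 scalings (trimmed mean of M values, median ratio, quantiles, TPM). They also covered eBayes without a trend or with a robust prior, a threshold of 0.10, the replicate number as a block, and each library left out. Limma's voom on the recovered fragments (mean of at least 10), a filter on fragments and a loess on GC content and length were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.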

Results

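Gene expression was measured by RNA sequencing in mouse vascular smooth muscle cells 48 hours after transfection with scramble siRNA (2 libraries) or with siRNA against the circular RNA circEsyt2 (2 libraries). The fragments assigned to genes numbered 2516428 and 4116791 in the scramble libraries and 3765056 and 3127224 in the circEsyt2 siRNA libraries. Between 16145 and 18783 genes were above 0 per library. Over the 11290 tested genes, the Pearson r of log2 values across genes was 0.972 between the scramble replicates and 0.931 between the circEsyt2 siRNA replicates, genes not being independent replicates. Both pairs differed by more than counting noise, with a chi-square per degree of freedom of 3.90 and 10.3, so each library, not each fragment, was counted as 1 sample. Such a spread can be technical and does not show that the libraries came from separate cultures. The comparison asks how expression differs between cells given the circEsyt2 siRNA and cells given the scramble siRNA.

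The host gene Esyt2, which encodes a protein tethering the endoplasmic reticulum to the plasma membrane, lies on chromosome 12 at 116281196 to 116391050 of GRCm38, plus strand. Its FPKM was 53.4 and 50.6 in the scramble libraries and 40.6 and 48.7 in the circEsyt2 siRNA libraries. The log2 fold change of Esyt2 was −0.22 (SE 0.13) and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.318). Over the 19 alternative fits the fold change ranged from −0.35 to −0.09. This row counts exons of the whole gene and checks nothing about the circle, whose own level was not analysed here. Pcbp1, which encodes an RNA-binding protein, measured 151 ± 2.48 FPKM with scramble siRNA and 171 ± 40.6 with circEsyt2 siRNA (SD, n = 2; adjusted p = 0.566). Trp53, the gene for p53, measured 43.0 ± 1.66 and 38.9 ± 3.32 FPKM (SD, n = 2; adjusted p = 0.474), so neither gene passed the test.

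Of the unfolded protein and integrated stress response list 15 of 29 tested members were higher and 6 lower with circEsyt2 siRNA, while of the contractile smooth muscle list 13 of 24 were lower and 1 higher, and of the type I interferon list 16 of 30 were lower and 0 higher. Camera called these 3 lists, and with an estimated correlation it called none of them (adjusted p = 0.376, adjusted p = 0.376 and adjusted p = 0.529). The estimated correlations were −0.0309, −0.00933 and 0.412, against the preset 0.01. That test rests on the 2 residual degrees of freedom of the fit and could call few lists. Its result for the stress response and contractile lists therefore does not show that correlated genes made their calls. Atf3, a transcription factor induced by stress, rose from 3.48 ± 1.78 to 55.0 ± 6.63 FPKM (SD, n = 2), and the kinase-like Trib3 rose from 4.22 ± 1.44 to 52.1 ± 9.91 FPKM. Fst, which encodes the activin antagonist follistatin, was 13.6-fold lower by mean FPKM, at 68.7 ± 7.27 against 5.06 ± 0.0538 FPKM. Gas1, a membrane protein gene linked to growth arrest, was 16.6-fold lower by mean FPKM, at 16.4 ± 0.282 against 0.988 ± 0.129 FPKM. Its circEsyt2 siRNA values rest on 10 and 10 fragments. On the log2(FPKM + 1) scale the fold changes of Fst and Gas1 were −3.52 and −3.13. In limma with Benjamini-Hochberg adjustment, 617 genes were higher and 820 lower with circEsyt2 siRNA, of 11290 tested, and 226 and 434 of them by at least 1 on the log2 scale. Without scramble replicate 1 or without scramble replicate 2 limma called 0 genes at the adjusted threshold, with 1959 and 2231 genes at an unadjusted p under 0.05, so every single-gene call named here was lost in those fits. The count was 405 higher and 622 lower without circEsyt2 siRNA replicate 1, and 272 higher and 228 lower without circEsyt2 siRNA replicate 2. Among the genes named below, eBayes without a trend also lost the calls of Cdc20, Rrm2, Ccne1, Bbc3, Timp2, Hnrnpa1, Pdlim7, Lgals3, Fn1, Mmp10, Rbm39, Il11 and Eng, and a fit with no filter on low values those of Ccne1, Bbc3 and Kdr.

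Besides Atf3 and Trib3, the 8 largest increases were Adm2, Cth, Chac1, Areg, Ndrg1 and Cxadr. Adm2 encodes the peptide adrenomedullin 2 and rose by 3.56 on the log2 scale (SE 0.25), Cth encodes an enzyme that makes cysteine and rose by 2.94 (SE 0.16), and Chac1 encodes a glutathione-degrading enzyme and rose by 2.65 (SE 0.19). Areg, the growth factor amphiregulin, rose by 2.51 (SE 0.22), and Ndrg1 and Cxadr rose by 2.46 and 2.44. The adjusted p of these genes lay between 0.00256 (Cth) and 0.00427 (Areg). The decreases included S100b, which encodes a calcium-binding protein and fell by 2.94 on the log2 scale (SE 0.19), and Sod3, which encodes extracellular superoxide dismutase and fell by 2.76 (SE 0.16). Vip, the gene of vasoactive intestinal peptide, fell by 2.72 (SE 0.22; adjusted p = 0.00390), and the heat shock gene Hspa1b fell by 2.70 (SE 0.38; adjusted p = 0.0119), though Hspa1b has a near-identical copy, Hspa1a, with which fragments can be shared. AC133103.5, whose symbol was not found in M21, had at least 11 and 6 fragments with scramble siRNA and 0 and 0 with circEsyt2 siRNA. Its length was solved as the smallest that gave whole fragment numbers, so these are minimum numbers. They put it at least 3.32-fold lower against a floor of 3 fragments per library (1.66-fold without scramble replicate 1 and 4.98-fold without scramble replicate 2). The call was lost without circEsyt2 siRNA replicate 2. The rule also selected Trdd1, an 11 bp segment with 1 and 1 against 0 and 0 fragments, for which no fold is given.

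**Figure D1:**
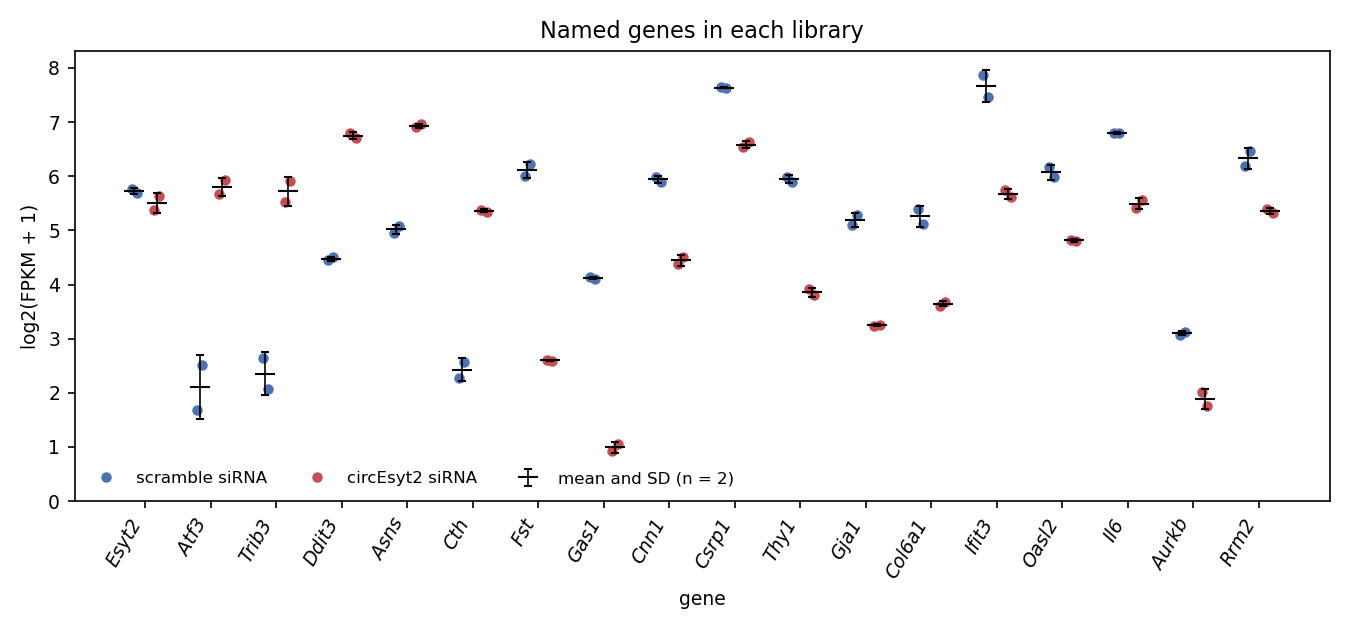
Log2(FPKM + 1) of 18 named genes in the scramble siRNA (blue) and circEsyt2 siRNA (red) libraries, with each point 1 library and the bars the mean and SD (n = 2). Atf3, Trib3, Ddit3, Asns and Cth sit higher with circEsyt2 siRNA, Esyt2 did not pass the test, and the other 12 genes sit lower.

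The list of unfolded protein and integrated stress response genes had 15 of its 29 tested members higher, 6 lower and 8 not called (camera's adjusted p = 0.376 with an estimated correlation). Ddit3, which encodes the stress transcription factor CHOP, went from 21.3 ± 0.578 to 107 ± 5.18 FPKM (SD, n = 2), and Asns, asparagine synthetase, from 31.4 ± 1.91 to 121 ± 3.16 FPKM. Chosen after their values were seen, Atf4, the transcription factor at the centre of the integrated stress response, rose by 1.47 on the log2 scale, and Slc7a5, an amino acid transporter, rose by 1.78. The 6 members that fell were Calr, Pdia6, Hsp90b1, Hyou1, Manf and Pdia4, which are known for protein folding in the endoplasmic reticulum. Of these, Calr fell by 0.72 and Hyou1 fell by 1.34, both chosen after their values were seen. With eBayes without a trend all 6 of these calls were lost, and without circEsyt2 siRNA replicate 2 those other than Calr. Pdia4 also lost its call with trimmed mean or median ratio scaling, with no filter on low values and with the replicate block. The median log2 fold change of the list was 0.65, with 0.53 in replicate 1 and 0.83 in replicate 2 relative to the scramble mean, and camera's adjusted p was 9.57e-05 with the preset correlation. There were 17 members higher and 7 lower when adjusted over the list alone.

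Contractile smooth muscle genes had 13 of 24 tested members lower, 1 higher and 10 not called (camera's adjusted p = 0.376 with an estimated correlation). Cnn1, the actin-binding calponin of differentiated smooth muscle, went from 60.5 ± 2.96 to 20.8 ± 1.45 FPKM (SD, n = 2; limma adjusted p = 0.00384), and Csrp1, a LIM protein of muscle differentiation, from 198 ± 1.26 to 95.0 ± 4.15 FPKM (adjusted p = 0.00470). Acta2 and Myh11, the smooth muscle actin and myosin genes chosen here after their values were seen, fell by 0.74 and 1.68 on the log2 scale, both calls lost with eBayes without a trend. Pdlim7, a PDZ and LIM protein gene, was the 1 member that rose, by 0.86, a call lost without circEsyt2 siRNA replicate 2. The list median was −0.86 and camera's adjusted p was 1.17e-07 with the preset correlation. Adjusted over the list alone, 16 members were lower and 1 was higher.

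Genes of dedifferentiated smooth muscle, the migratory state of cultured cells, had 10 of 24 tested members lower, 3 higher and 11 not called (camera's adjusted p = 0.398 with an estimated correlation). The gap junction gene Gja1 went from 35.5 ± 3.27 to 8.48 ± 0.13 FPKM (SD, n = 2), and Ly6a, a surface marker of progenitor-like cells, from 619 ± 1.03 to 253 ± 43.2 FPKM. Lgals3, Fn1 and Klf5 were the 3 members that rose, and of these the transcription factor gene Klf5 rose by 1.54 and the fibronectin gene Fn1 by 0.89, both chosen after their values were seen, and all 3 calls were lost without circEsyt2 siRNA replicate 2. The list median was −0.60, and −0.39 without circEsyt2 siRNA replicate 2, and camera's adjusted p was 0.00614 with the preset correlation. In that list 12 members were lower and 3 higher adjusted over the list alone. Fibroblast markers, which share Lum, Dcn and Pdgfra with that list, had 4 of 10 tested members lower and 0 higher, and 5 were lower adjusted over the list alone. Thy1, a surface glycoprotein gene, fell by 2.09 on the log2 scale, and Mfap5, a microfibril gene, fell by 1.22. The fibroblast list median was −0.997 and camera's adjusted p was 0.000761 (adjusted p = 0.409 with an estimated correlation), and with no filter on low values that median was −0.36.

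Genes of the type I interferon response, the antiviral programme that transfected RNA can induce, had 16 of 30 tested members lower, 0 higher and 14 not called (camera's adjusted p = 0.529 with an estimated correlation). Without untransfected cells, a fall with circEsyt2 siRNA cannot be told apart from a rise with scramble siRNA. Ifit3, an interferon-induced antiviral gene, went from 204 ± 42.2 to 50.2 ± 3.31 FPKM (SD, n = 2), and Oasl2 of the oligoadenylate synthetase family from 66.7 ± 6.52 to 27.1 ± 0.409 FPKM. Irf7, a transcription factor gene of this response chosen after its values were seen, fell by 1.13 on the log2 scale. The list median was −0.81 and camera's adjusted p was 1.73e-09 with the preset correlation of 0.01. That p leans on the preset, since the estimated correlation of this list was 0.412. The fry test did not call the list (adjusted p = 0.0557). In this list 22 members were lower and 1 was higher adjusted over the list alone. Inflammatory genes of the NF-kB list showed 13 of 28 tested members lower and 1 higher, the cytokine gene Il11, whose call was lost without circEsyt2 siRNA replicate 2. Il6, a cytokine gene, went from 110 ± 0.862 to 44.0 ± 3.14 FPKM, and Il1rl1, the interleukin 33 receptor gene, from 125 ± 15.8 to 42.5 ± 1.87 FPKM. The median of this list was −0.55 and camera's adjusted p was 9.57e-05 (adjusted p = 0.409 with an estimated correlation). Adjusted over the list alone, 14 were lower and 2 higher.

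**Figure D2:**
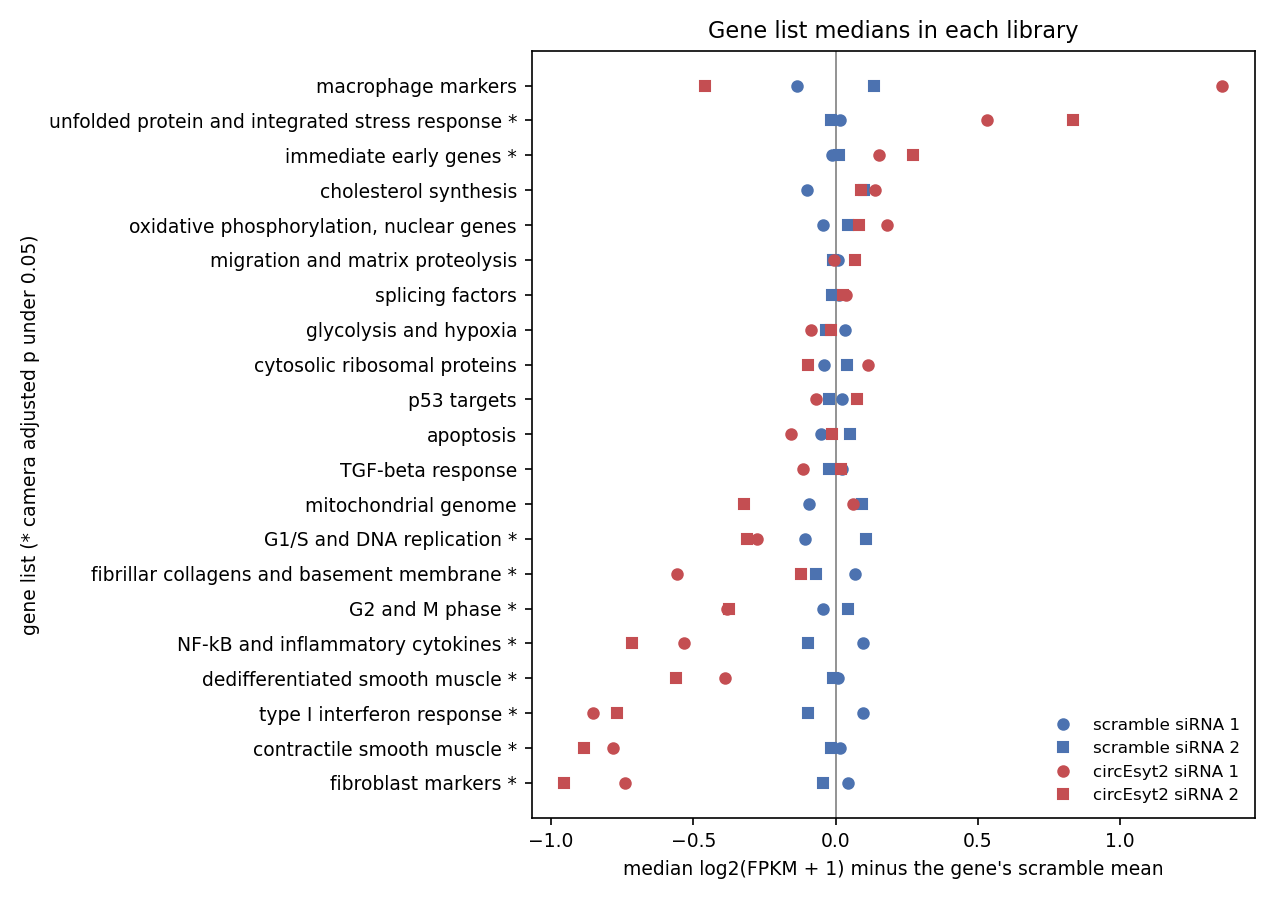
Median over each tested gene list of log2(FPKM + 1) minus the gene's scramble mean (x axis), for each library (circles replicate 1, squares replicate 2). The contractile list sits at −0.78 and −0.89 and the stress response list at 0.53 and 0.83 in the circEsyt2 siRNA libraries, while macrophage markers sit at 1.36 in replicate 1 and −0.46 in replicate 2.

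Cell cycle genes were lower in part. Of the 30 genes of G2 and M phase, 7 fell and 0 rose, and of the 28 tested genes of G1/S and DNA replication, 4 fell and 0 rose. Aurkb, a mitotic kinase gene, went from 7.58 ± 0.234 to 2.73 ± 0.479 FPKM (SD, n = 2; limma adjusted p = 0.0173), and Cdc20, an activator of the anaphase-promoting complex, from 21.5 ± 1.89 to 11.4 ± 0.0669 FPKM. Rrm2, a ribonucleotide reductase subunit gene, fell by 0.97 on the log2 scale and Ccne1, the cyclin E1 gene, by 0.83, and these 4 calls were lost without circEsyt2 siRNA replicate 2. For G2 and M phase the median was −0.36 and camera's adjusted p was 0.000166 (adjusted p = 0.376 with an estimated correlation). For G1/S the median was −0.25 and camera's adjusted p was 0.0446 (adjusted p = 0.599 with an estimated correlation). Adjusted over the list alone, the counts were again 7 and 4 lower and 0 higher. The G1/S call was lost under quantile normalization, with the replicate block, and without scramble replicate 2 or either circEsyt2 siRNA replicate, and the G1/S median was −0.39 without scramble replicate 1.

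Collagen and basement membrane genes had 8 of 28 tested members lower, 0 higher and 20 not called. Col6a1, a chain of the microfibrillar collagen VI, went from 37.6 ± 5.13 to 11.5 ± 0.431 FPKM (SD, n = 2), and Col12a1, a fibril-associated collagen, from 85.5 ± 8.76 to 31.9 ± 3.48 FPKM. The list median was −0.36 and camera's adjusted p was 0.00678 (adjusted p = 0.828 with an estimated correlation). There were 10 members lower and 2 higher adjusted over the list alone. The median was −0.56 in circEsyt2 siRNA replicate 1, the library with high hepatocyte markers described with the cell type markers, and −0.12 in replicate 2. The call was lost without circEsyt2 siRNA replicate 1, where the median was −0.12, without scramble replicate 1, and after removing a trend on GC content and length.

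Immediate early genes, the transcripts that answer stimuli first, had 6 of 25 tested members higher and 2 lower. Dusp4, a MAP kinase phosphatase gene, went from 8.79 ± 0.737 to 29.6 ± 0.948 FPKM (SD, n = 2), and Atf3 belongs to this list and to the stress response list. The 2 members that fell were Nr4a2 and Nr4a1, orphan nuclear receptor genes, and Nr4a1 fell by 1.18 on the log2 scale, a call lost without circEsyt2 siRNA replicate 2. For this list the median was 0.18 and camera's adjusted p was 0.0232 (adjusted p = 0.675 with an estimated correlation). Adjusted over the list alone, 10 were higher and 3 lower. This call was lost without scramble replicate 1 and without circEsyt2 siRNA replicate 2.

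Genes of the p53 targets list moved in both directions, with 6 of 30 tested members higher and 10 lower, the same counts adjusted over the list alone. Sesn2, a stress-induced regulator of mTORC1, went from 14.9 ± 1.53 to 42.4 ± 0.183 FPKM (SD, n = 2; limma adjusted p = 0.00453), and Fas, the death receptor gene, from 51.5 ± 5.50 to 17.6 ± 0.0842 FPKM (adjusted p = 0.00427). The list median was −0.02 and camera did not call the list (adjusted p = 0.722, and adjusted p = 0.898 with an estimated correlation). Both look for movement in 1 direction, so they do not show that the list was unchanged. In either direction limma called 16 of the 30 members, against 12.7% of all tested genes. Apoptosis genes, of which Bax, Bbc3, Pmaip1 and Fas are also on the p53 list, had 1 of 26 tested members higher and 4 lower, and the same adjusted over the list alone. Bbc3, which encodes the pro-apoptotic protein PUMA, rose by 1.04 on the log2 scale (SE 0.22; adjusted p = 0.0358), a call lost without either circEsyt2 siRNA replicate. The apoptosis list was not called (camera adjusted p = 0.406, and adjusted p = 0.686 with an estimated correlation).

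Migration and matrix proteolysis genes had 6 of 30 tested members higher and 3 lower, and 7 and 6 adjusted over the list alone. Timp2, a metalloproteinase inhibitor gene, fell by 0.77 on the log2 scale, and Plau, the urokinase gene, fell by 1.78, whereas the metalloproteinase gene Mmp10, chosen after its values were seen, rose by 0.84, a call lost without either circEsyt2 siRNA replicate. Splicing factors had 3 of 34 tested members higher and 2 lower, and 4 and 4 adjusted over the list alone. Hnrnpa1 and Hnrnpd, genes of heterogeneous nuclear ribonucleoproteins, fell by 0.84 and 1.07 on the log2 scale (limma adjusted p = 0.00869 and 0.0119), and Rbm39, an RNA-binding protein gene chosen after its values were seen, rose by 0.79, and these 3 calls were lost without circEsyt2 siRNA replicate 2. Camera called neither list (adjusted p = 0.768 for migration and 0.722 for splicing, and adjusted p = 0.898 with an estimated correlation for both). In both lists the median was above 0, at 0.04 and 0.03, and the mean below 0, at −0.02 and −0.01.

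Of the other context lists, camera called none of TGF-beta response, glycolysis and hypoxia, cholesterol synthesis, cytosolic ribosomal proteins, nuclear genes of oxidative phosphorylation and the mitochondrial genome, the smallest adjusted p being 0.0839 for oxidative phosphorylation (adjusted p = 0.838 with an estimated correlation). TGF-beta response genes went both ways, with 5 of 26 tested members higher and 7 lower, and 9 and 9 adjusted over the list alone. Ctgf, a matricellular gene, rose by 1.17 on the log2 scale and Id1, an inhibitor of differentiation, fell by 1.29, both chosen after their values were seen. Glycolysis and hypoxia genes had 2 higher and 3 lower of 28, and 4 and 8 adjusted over the list alone, with a median of 0.02 and a mean of −0.03. Ribosomal protein genes had 3 of 42 higher and 0 lower, and 1 and 0 adjusted over the list alone, with a median of −0.01 and a mean of 0.05. Cholesterol synthesis had 1 of 24 lower and oxidative phosphorylation 2 higher and 1 lower of 32, the same adjusted over the list alone. Of the 13 mitochondrially encoded genes limma called 0, with 1 at an unadjusted p under 0.05, and voom called 0 of 12.

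Genes known from hepatocytes stood high in circEsyt2 siRNA replicate 1. Alb, the serum albumin gene, measured 2083 FPKM in that library against 9.16 and 1.66 in the scramble libraries and 65.7 in circEsyt2 siRNA replicate 2. Ttr, the transthyretin gene, measured 172 FPKM against 1.34, 0 and 5.93, and Cyp2e1, a hepatic cytochrome P450 gene, 111 against 0.552, 0.563 and 2.07. The 30 hepatocyte markers, a list made after the data were seen, took 0.965% of the fragment total of that library, 0.00572% and 0.00389% of the scramble totals and 0.0323% of that of circEsyt2 siRNA replicate 2. Limma called 0 of the 30 different between the groups, with 17 at an unadjusted p under 0.05, and voom called 0. Over all genes, 334 were at least 2 times higher in circEsyt2 siRNA replicate 1 than in each other library (FPKM + 1, at least 20 fragments), against 9, 7 and 6 for scramble replicates 1 and 2 and circEsyt2 siRNA replicate 2.

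**Figure D3:**
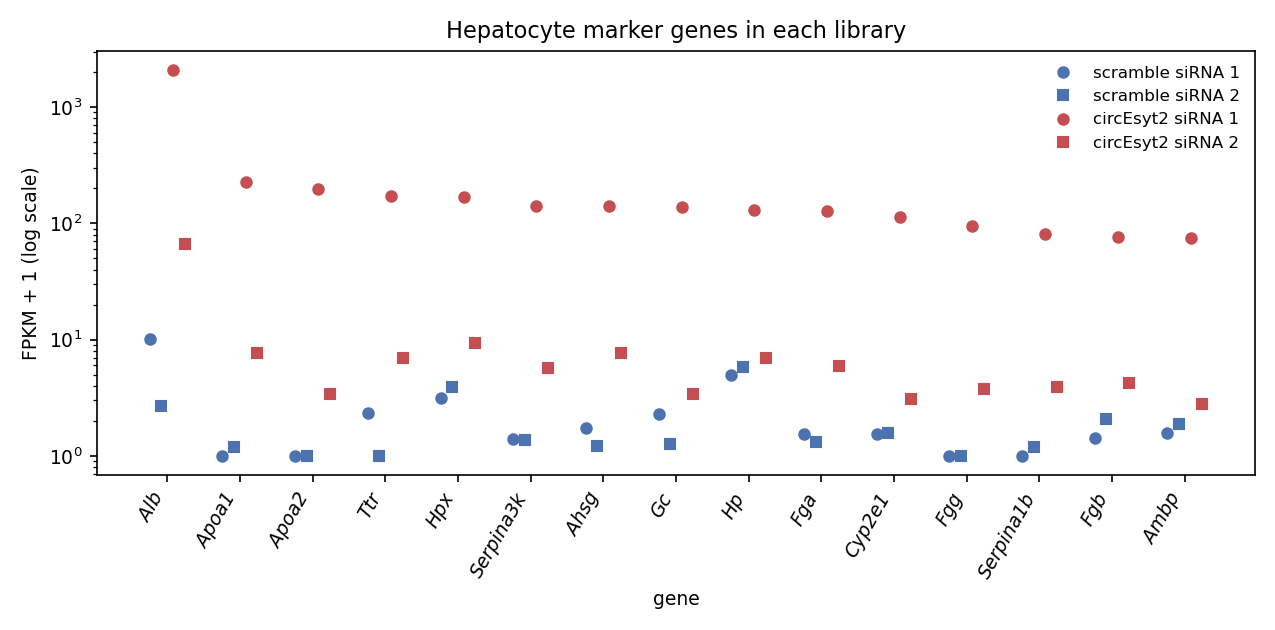
FPKM + 1 (log scale) of the 15 hepatocyte marker genes highest in circEsyt2 siRNA replicate 1, for each of the 4 libraries. Alb stands at 2083 FPKM in circEsyt2 siRNA replicate 1 and at 65.7 in replicate 2, and the scramble libraries lie at 9.16 and 1.66 FPKM.

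Among the cell type lists fixed beforehand, macrophage markers had a median of 1.36 in circEsyt2 siRNA replicate 1 and −0.46 in replicate 2 relative to the scramble mean. Lyz2, the lysozyme gene of macrophages, measured 21.4 FPKM in replicate 1 and between 0.923 and 1.21 in the other libraries. Limma and voom each called 0 of the 5 macrophage markers, with 0 at an unadjusted p under 0.05, and camera's adjusted p was 0.728 (adjusted p = 0.898 with an estimated correlation). Epithelial and mesothelial markers had medians of 1.43 in replicate 1 and 0.10 in replicate 2 over 4 tested members, of which limma and voom called 0 and 1 had an unadjusted p under 0.05. Of 4 endothelial markers tested Kdr, a VEGF receptor gene, rose by 1.20 on the log2 scale and Eng, the endoglin gene, fell from 20.3 ± 4.34 to 9.53 ± 0.0707 FPKM (SD, n = 2), both calls lost without either circEsyt2 siRNA replicate, and that of Kdr with the replicate block. Of the striated muscle markers 1 was tested, the skeletal actin gene Acta1, which rose by 1.01, a call lost with voom and without circEsyt2 siRNA replicate 2. Limma called 0 of 4 adipocyte markers, with 1 at an unadjusted p under 0.05 and 1 of 5 called by voom, and 0 lymphocyte markers reached the filter. The endothelial, epithelial, adipocyte, lymphocyte and striated muscle lists, 5 in all, were too small for camera.

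Of the 21 lists tested, camera with the preset correlation called 2 higher and 8 lower. With an estimated correlation 0 of the 10 called lists held at the adjusted threshold, with 2 lists at an unadjusted p under 0.05. With only 2 residual degrees of freedom that test could call few lists, so it cannot decide whether these calls hold. Among the called lists the estimated correlation was highest for collagens (0.416) and type I interferon genes (0.412), far above the preset 0.01. The fry test, which asks whether a list's genes move on balance in 1 direction, gave an adjusted p under 0.05 for 6 of the 10, namely the contractile, dedifferentiated, G2 and M phase, NF-kB, stress response and fibroblast lists. It did not call the type I interferon, collagen, G1/S and immediate early lists (fry adjusted p = 0.0557, 0.115, 0.114 and 0.111).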

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

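Voom on whole fragments, the filter on fragments and the GC and length correction were chosen after seeing the data. edgeR and DESeq2, planned if the data held counts or whole reads could be recovered, were not run although fragments were recovered, because the deposited unit is FPKM. Voom on those fragments, run in their place, called 901 genes higher and 1166 lower. In the 19 alternative fits 0 of the 1437 called genes changed direction among those tested. The genes were called in the libraries that these fits reuse, so a kept direction was nearly fixed in advance and is no independent support. Counts were 203 higher and 374 lower with eBayes without a trend, and 1129 and 1348 at an adjusted p under 0.10. With the replicate block they were 404 and 604. The titles share only replicate numbers, and the replicate differences of the 2 groups had a correlation across genes of −0.0507, so the samples were not treated as paired. Leaving out 1 library gave 0 to 405 genes higher and 0 to 622 lower, and 1 to 3 lists called higher. Limma called 0 genes without scramble replicate 1 and without scramble replicate 2, with 1959 and 2231 at an unadjusted p under 0.05. The spread in those fits came from the circEsyt2 siRNA pair alone, whose replicate differences had an SD of 0.637 against 0.402 in the scramble pair, and a lone library is assumed to vary like the other group. That pair includes replicate 1, where 334 genes were at least 2 times higher than in each other library. Whether that library caused the lost calls was not tested. Without circEsyt2 siRNA replicate 1, 862 of the calls were also made and 1431 of 1431 tested kept their direction. Lists called higher and lower numbered 0 and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and 1 and 5 with fry. Of the 10 called lists 7 kept their call in the 19 fits, and collagens, G1/S and immediate early genes did not. Of 74 called genes named in the text, 74 lost the call without either scramble library, 26 without circEsyt2 siRNA replicate 2, 4 without circEsyt2 siRNA replicate 1 and 23 without the trend. Some uncalled medians near 0 changed sign, and the cause was not tested. p53 targets were at 0.0638 with a mean FPKM of at least 5, at 9.45e-05 after GC and length correction and from −0.0699 to 0.0746 with a library left out. TGF-beta response was at 0.0565 with a mean FPKM of at least 5 and from −0.164 to 0.0190 with a library left out. Ribosomal proteins were at 0.0146 with the trimmed mean, at 0.00930 with the median ratio and from −0.0965 to 0.113 with a library left out. Glycolysis was at −0.00753 with quantiles, −0.0213 with TPM, −0.00714 with voom and from −0.0864 to 0.0782 with a library left out. Splicing factors were at −0.00852 with TPM and from 0.0251 to 0.107 with a library left out. With a library left out, migration ranged from −0.00610 to 0.0970, cholesterol synthesis from −0.0162 to 0.224, the mitochondrial genome from −0.322 to 0.0624 and Pcbp1 from −0.0841 to 0.403. Depth limits low genes, since 22 called genes had under 10 fragments on average.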

Other observations

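The lists of hepatocyte, Kupffer and liver endothelial, erythroid, tRNA synthetase, NRF2, lysosome and heat shock genes, and the tests of the hepatocyte genes, of the collagen list against liver material, of the other called lists and of the receptor genes, and the fits of these lists with a library left out, were chosen only after the data were seen. Aminoacyl-tRNA synthetase genes, whose enzymes charge tRNAs with amino acids, had 11 of 20 tested members higher and 1 lower with circEsyt2 siRNA. Rars, the arginyl-tRNA synthetase gene, measured 56.9 and 59.5 FPKM with scramble siRNA and 133 and 134 with circEsyt2 siRNA. Over the 20 members the median was 0.73, and camera's adjusted p over the 5 added lists tested was 1.34e-05 (adjusted p = 0.395 with an estimated correlation). The 5 include the hepatocyte list. As these lists were chosen after the data were seen, which the adjustment does not cover, their camera p-values are descriptive only. Lysosome genes had 11 of 30 higher and 0 lower, with a median of 0.37 and a camera adjusted p of 1.49e-05 (adjusted p = 0.186 with an estimated correlation). Among them Sqstm1, an autophagy receptor gene, rose by 1.78 on the log2 scale and Ctsl, the cathepsin L gene, by 0.96. As in the report, calls of single genes given here were lost without either scramble library.

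NRF2 targets, genes of the oxidative stress response, had 5 of 20 tested members higher and 2 lower, with a camera adjusted p of 0.0210 (adjusted p = 0.302 with an estimated correlation). Without circEsyt2 siRNA replicate 1 it was 0.0315 over the genes that then pass the filter and 0.0543 over the genes tested with all libraries. Slc7a11, a cystine transporter gene that is also on the stress response list, rose by 1.65 on the log2 scale, while the sulfiredoxin gene Srxn1 fell by 1.03, a call lost without circEsyt2 siRNA replicate 2. Heat shock chaperone genes had 1 of 18 higher and 4 lower and were not called as a list (camera adjusted p = 0.241, and adjusted p = 0.470 with an estimated correlation). Hspb8, a small heat shock protein gene, rose by 0.87 and Cryab, the alpha-B crystallin gene, fell by 0.84. Both calls were lost with eBayes without a trend, and that of Cryab also without circEsyt2 siRNA replicate 2. The 7 genes named in these paragraphs were chosen after their values were seen.

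Hepatocyte genes stood high in circEsyt2 siRNA replicate 1, with a list median 5.54 above the scramble mean on the log2 scale, and 1.24 above it in replicate 2. As the list was made after this excess was seen, and 16 of its 30 members pass the filter without that library, a list test of these genes is not used. Replicate 2 held a median of 2.94% of the excess of replicate 1 over the 30 markers (quartiles 1.56% and 3.52%, smallest −1.65%, largest 4.83%). These values argue against a response to the siRNA as the source of the excess in replicate 1. A response of the size seen in replicate 2 stays open, and whether liver material also reached that library was not tested. A candidate explanation is liver RNA or liver library fragments mixed into the library, where 100% of the 30 markers lay at least 8-fold above both scramble libraries, but the list was made after the excess was seen, so this value restates it and the explanation stays open. Of 14 Kupffer and liver endothelial and 7 erythroid genes 1 each was tested and not called, Clec4f at 3.12 FPKM there and 0.259 to 0.492 elsewhere, and Hbb-bs at 10.0 against 0 to 1.58.

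The gene lists called between the groups were weighed against liver material in circEsyt2 siRNA replicate 1 and against a trend on GC content or length. The 9 called lists other than collagens kept at least 94.0% of their median without circEsyt2 siRNA replicate 1 and at least 85.6% after the GC and length correction, which argues against either as their whole cause, although the G1/S call was lost without that library (median −0.31, adjusted p = 0.0788). In replicate 1 the collagen list lay −0.55 from the median of all tested genes on the log2 scale, more than a dilution shared by all genes allows, although its median without that library was −0.12 (adjusted p = 0.0791) and without scramble replicate 1 −0.21 (adjusted p = 0.0508). After the correction its median went from −0.36 (quartiles −0.89 and 0.07) to −0.17 (quartiles −0.77 and 0.20), 47.0% of its size, and the call ended as the median moved toward 0 and both quartiles moved up (adjusted p = 0.0985), so a GC or length trend may account for part of it. An effect of the siRNA on these lists stays open, and the design has 1 siRNA against circEsyt2, so losing the circle and other effects of that siRNA were not separated. It also has 1 scramble siRNA and no untransfected cells, so effects of the scramble siRNA were not separated from them.

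Olfactory and vomeronasal receptor genes, which smooth muscle is not known to use, held fragments in each library, 1581 and 4605 with scramble siRNA and 3263 to 5574 with circEsyt2 siRNA over 1134 olfactory receptor genes. Scaled by library total, scramble replicate 2 and circEsyt2 siRNA replicates 1 and 2 lay at 1.78, 2.36 and 1.66 times scramble replicate 1. The lower circEsyt2 siRNA library lay at 0.933 times the higher scramble library, within the 1.78-fold between the scramble libraries, so a response to the siRNA stays open. Untranscribed sequence such as genomic DNA is a candidate source, since each library's value relative to scramble replicate 1 differed by at most 1.24-fold between olfactory receptor, vomeronasal receptor and repeat-like predicted genes. Mismapped reads from repeats were not tested and stay open.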
